A study of Rattus norvegicus with 8 samples.

How the data were processed

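RNA was sequenced from the sinoatrial node, the pacemaker tissue of the right atrium, of Dahl salt-sensitive rats, an inbred strain that develops hypertension on a salt-rich diet. The Control group (n = 4) ate chow with 0.4% NaCl and the HFpEF group (heart failure with preserved ejection fraction, n = 4) ate chow with 8% NaCl, both for 11 weeks. Per the labels' protocols, total RNA was depleted of ribosomal RNA before library construction, so transcripts without a poly(A) tail can also appear. The labels do not state that each library came from its own animal, so p-values measure the spread between these libraries.

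The values are the expected counts per gene that the authors deposited as 1 table for the series, with no normalization. RSEM estimates such counts by sharing out reads that fit several genes, so a value need not be whole. Bowtie2 2.1.0, RSEM 1.2.15 and the rn6 genome build are named in the submitters' processing notes. The annotation release, read filters and strand setting are not given in the sources used here. Without a stated strand setting, it is not known whether reads of overlapping and antisense genes were told apart. The table held 32285 Ensembl gene identifiers, and each of its 8 columns matched 1 library's title.

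The table does not pair its identifiers with gene names, and the reference gene table used here carried no Ensembl identifiers to match them to, so 0 of the 32285 could be named. Gene symbols, positions, lengths and GC contents were therefore not used. The 41 gene lists fixed before the data were examined (pacemaker channels, calcium handling, matrix, cell type markers and others), and their set tests, were not run. The rule for named genes asked for symbols or, without regard to symbols, for the 5 genes with the smallest p. Only the 2 rising genes with the smallest p are printed from it, by identifier. The 2 falling genes with the smallest p were added after the values were seen.

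Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr (16313 genes, holding 99.95% of all counts), and libraries were scaled by TMM. HFpEF was compared with Control by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust = FALSE), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; a gene past it is said to be called. Normalised CPM were computed by edgeR's cpm function from the TMM-scaled library totals. The share of genes with some difference was estimated from the p-values by limma's propTrueNull (convest). Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Single values per library were compared by exact two-sided permutation tests over the 70 splits. To see whether changes recurred in separate libraries, the comparison was also fitted on sets of 2 Control and 2 HFpEF libraries and set against the fit on the remaining 4, in 18 pairings that share no library. A count was taken as whole within 0.005.

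Total counts ran from 31774820 to 38889395 per library. A count of 0 allows a level of up to 3 counts, or 0.0771 to 0.0944 CPM, which covers counting error only, since the deposited values carry no molecular identifiers. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom of 19.4 to 87.7 over pairs). This shows that none was a resampled copy of another, not that each came from its own animal. All 8 were used as separate libraries.

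On counts simulated for this comparison from the means, depths and dispersions of the 16313 tested genes, edgeR recovered 38.8% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.4% of those changed 4-fold. Of its calls, 5.52% were unchanged genes, against 25.9% for DESeq2 and 6.16% for limma-voom. Only 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, as many up as down, with the same dispersion in both groups. The shares hold for that setting and need not carry over to data with more changed genes or unequal spread.

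Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample weights, RLE and upper quartile scaling, no filter and a stricter filter on low counts, the replicate number as a block, robust = TRUE, a threshold of 0.1, 1 surrogate variable (sva 3.50.0), and each library left out in turn. The groups share the numbers 1 to 4, with nothing in the labels to say that these pair the libraries. Leaving out the 10 genes with the most counts, and leaving out genes with a non-whole expected count, were chosen after seeing the data. The first replaces a setting, fixed earlier, that would also have left out the mitochondrial genes by name.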

Results

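Expression was measured by total RNA sequencing in the sinoatrial node of Dahl salt-sensitive rats, 4 libraries from rats on normal chow (Control) and 4 from rats on high-salt chow that modelled heart failure with preserved ejection fraction (HFpEF). No group ate high-salt chow without the disease model. Effects of salt intake, hypertension and heart failure therefore cannot be told apart in any difference below. The total expected count was 36839564 ± 1388872 in Control and 34676828 ± 2218855 in HFpEF (SD, n = 4 each). This difference did not pass an exact two-sided permutation test (p = 0.171, adjusted p = 0.286 over 5 library measures). Between 20178 and 21235 genes had a count in each library. The 10 most counted genes took 27.9% ± 1.36 of the counts in Control and 29.1% ± 1.65 in HFpEF (SD, n = 4 each; exact permutation p = 0.314). The 2 most counted genes took 11.7% ± 1.11 in Control and 14.2% ± 1.91 in HFpEF (SD, n = 4 each; exact permutation p = 0.0857).

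The series asks how the node's transcriptome differs between control and HFpEF animals. The first principal component, which held 33.2% of the variance in log2 CPM, separated the groups without overlap. Control libraries lay between -30.9 and -17.2 and HFpEF libraries between 10.6 and 51.6. The exact two-sided permutation p was 0.0286, the smallest that 70 splits allow, and 0.143 after adjustment over the 5 library measures. HFpEF replicate 2 lay farthest from Control on this axis, and HFpEF replicates 1 and 4 lay nearest to it.

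**Figure D1:**
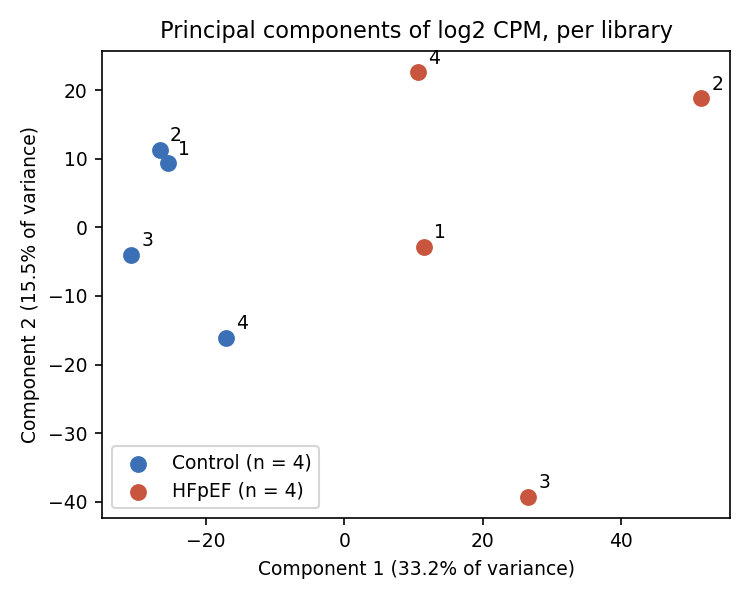
Each point is 1 library, placed by the first (33.2% of variance) and second (15.5%) principal components of log2 CPM, coloured by group and marked with its replicate number. The Control libraries lie between -30.9 and -17.2 on the first axis and the HFpEF libraries between 10.6 and 51.6.

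In HFpEF, 316 of the 16313 tested genes (1.94%) changed, 251 of them higher and 65 lower than in Control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). With 1 library left out in turn, between 21 and 234 were higher and between 0 and 98 lower. The median log2 fold change was 0.95 for the 251 rising genes (quartiles 0.64 and 1.56) and -0.45 for the 65 falling genes (quartiles -0.96 and -0.36). Of the rising genes, 118 changed by at least 1 on the log2 scale and 33 by at least 2, while 15 of the falling genes changed by at least 1 and 0 by at least 2. None of the 316 genes was at 0 in all libraries of a group. In 4 of the rising genes the Control mean was 3 counts or fewer per library, so their fitted folds, all of at least 2 on the log2 scale, are not firm. Without them 114 rising genes changed by at least 1 and 29 by at least 2. The smallest called changes were 0.26 for a rise and -0.23 for a fall.

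The gene with the smallest p was ENSRNOG00000014288. It rose 2.65-fold, from 249 ± 9.71 normalised CPM in Control to 659 ± 57.9 in HFpEF (SD, n = 4 each), a log2 fold change of 1.40 with a standard error of 0.07 (edgeR adjusted p = 0.000242). ENSRNOG00000033192 rose 1.91-fold, from 13.4 ± 0.915 to 25.6 ± 2.04 CPM (SD, n = 4 each; edgeR adjusted p = 0.00396). Among falling genes, ENSRNOG00000009450 went from 359 ± 28.7 to 225 ± 25.6 CPM (SD, n = 4 each), a log2 fold change of -0.67 with a standard error of 0.09 (edgeR adjusted p = 0.0194). ENSRNOG00000016866 went from 84.4 ± 4.87 to 62.1 ± 3.15 CPM (SD, n = 4 each), a log2 fold change of -0.44 (edgeR adjusted p = 0.0194). In each of the 4 genes the HFpEF and Control libraries did not overlap, and every expected count was whole. The 20 genes with the smallest p all rose. ENSRNOG00000014288 was called in all 20 alternatives. ENSRNOG00000033192 lost its call with the replicate number as a block (edgeR adjusted p = 0.0553), and both falling genes lost theirs with that block (edgeR adjusted p = 0.0966) and without Control replicate 1 or Control replicate 3.

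**Figure D2:**
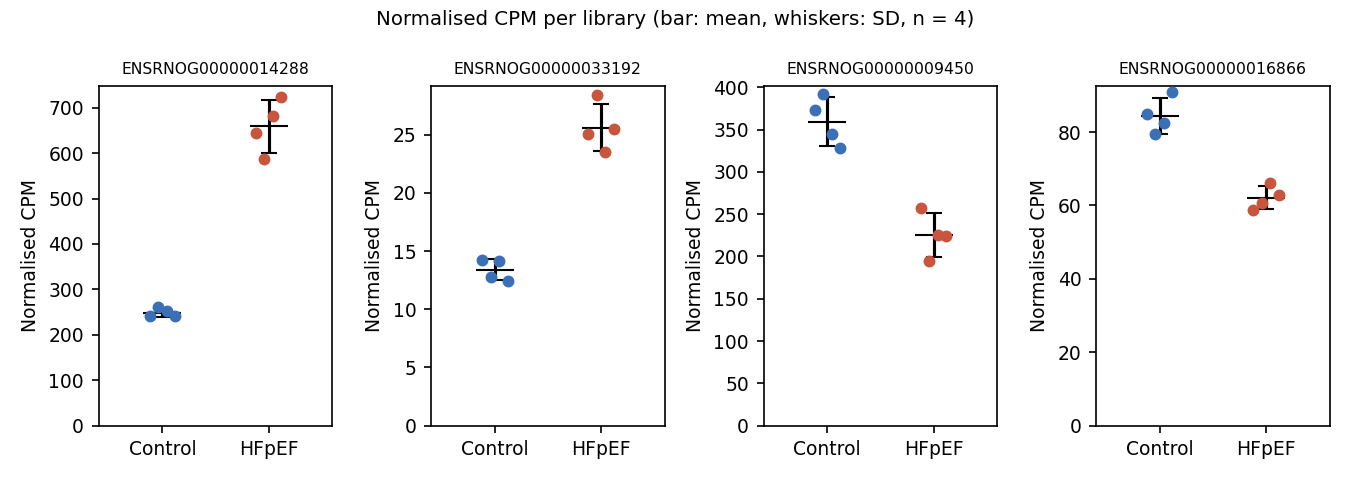
Normalised CPM (vertical axes, from 0) of 4 genes in each Control and HFpEF library. Points are libraries, the horizontal bar is the group mean and the whiskers are the SD (n = 4). The first 2 genes, ENSRNOG00000014288 and ENSRNOG00000033192, are higher in every HFpEF library and the other two are lower.

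Rising genes outnumbered falling genes at every expression level. Among genes with a mean of 1 to 4 CPM, 68 rose and 8 fell, so that 89.5% of the called genes rose (exact 95% binomial interval 80.3 to 95.3). Between 16 and 64 CPM 63 rose and 25 fell (71.6%, interval 61.0 to 80.7). From 64 to 256 CPM 18 rose and 10 fell, and above 256 CPM 8 rose and 4 fell. The intervals of these last groups, 44.1 to 81.4 and 34.9 to 90.1, include an even split. Called genes do not vary independently of one another, so these intervals cover counting error only. Rising genes had a median of 8.77 CPM and falling genes one of 20.9 CPM.

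**Figure D3:**
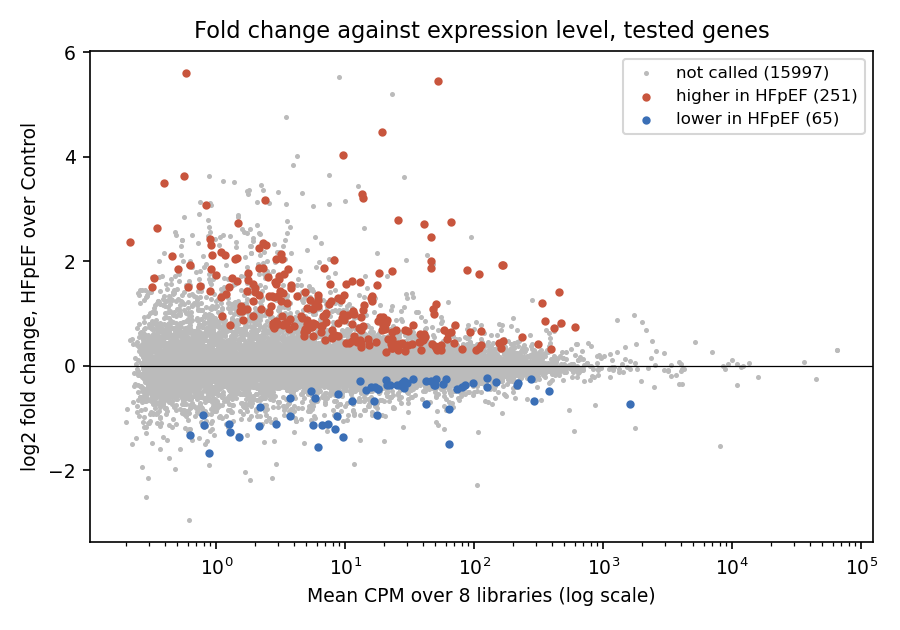
The log2 fold change of HFpEF over Control (vertical axis) against the mean CPM over 8 libraries (horizontal axis, log scale), 1 point per tested gene. The 251 called rising genes spread to larger changes than the 65 called falling genes. Genes that were not called are grey.

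More genes than those called had a small p or no overlap between the groups. An unadjusted p under 0.05 was reached by 3191 genes, against 816 expected with no difference, and 57.3% of them were higher in HFpEF. All 4 HFpEF libraries lay above all 4 Control libraries in 1100 genes and below them in 934. Together these were 12.5% of the tested genes, where chance gives 2.86% on average over splits of the libraries. Genes vary together, so in a single split this share and the 816 genes can lie far from their averages by chance. Other splits were not compared on either. All 316 called genes were among them, which a small p with 4 libraries per group makes likely. The share of tested genes with some difference was estimated from the p-values at 37.3%. This estimate uses the same p-values of genes that vary together, so it too can lie far from the true share.

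The direction of change in the genes with the smallest p mostly recurred between libraries. In the 18 pairings of sets that shared no library, the log2 fold changes of the 2 sets correlated across genes with a median r of 0.404 (range 0.318 to 0.444); genes are not independent replicates. Of the 500 genes with the smallest p in a set, a median of 88.7% had the same sign in the other set (range 73.6 to 94.4 over 36 directions). For genes that were higher the median share was 91.3% (range 71.1 to 96.2). For genes that were lower it was 80.6% (range 55.0 to 93.3), where chance gives an even split, so recurrence of the falls was weak in some pairings. The set with the most called genes (186) held Control replicates 1 and 2 and HFpEF replicates 2 and 3. Its r was the lowest, 0.318, and 71.1% of its higher and 85.6% of its lower top genes kept their sign. Other splits of the libraries were not put through this comparison, so they give the recurrence no baseline.

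The number of called genes varied with the libraries included, most with those of Control. It was 22 without Control replicate 1, 89 without Control replicate 2, 24 without Control replicate 3, 157 without Control replicate 4, 332 without HFpEF replicate 1, 186 without HFpEF replicate 2, 157 without HFpEF replicate 3 and 245 without HFpEF replicate 4. The falling genes went from 65 to 1, 4, 0 and 39 without Control replicates 1 to 4 in turn, and to 98, 18, 18 and 51 without HFpEF replicates 1 to 4. The rising genes went from 251 to 21, 85, 24 and 118, and to 234, 168, 139 and 194. The fit gives each gene a single dispersion for both groups, while HFpEF libraries spread more than Control libraries (ratio of median variances 2.11). Leaving out a Control library can therefore raise the pooled spread, and leaving out an HFpEF library can lower it. The drop in calls without a Control library does not by itself show that single Control libraries carry the result. Where edgeR called 0 falling genes, without Control replicate 3, 2522 genes in either direction had an unadjusted p under 0.05. With the replicate number as a block edgeR called 6 rising and 0 falling genes, with 2568 at an unadjusted p under 0.05. DESeq2 called 1247 genes, 861 of them higher and 386 lower, with all 316 genes among them. That split puts the rising share at 69.0%, against 79.4% with edgeR. All 316 genes kept their direction in every alternative that tested them. None of them overlapped between the groups, so leaving out a library could hardly have reversed a direction, and this adds no support.

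**Figure D4:**
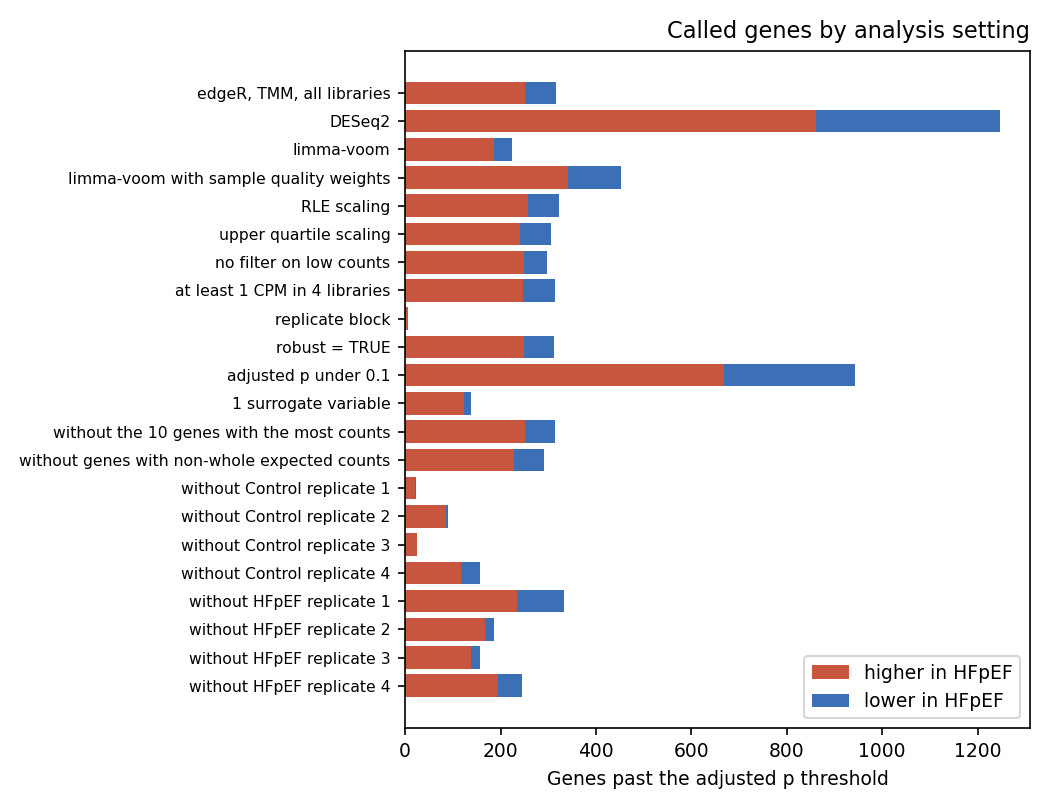
The number of called genes (horizontal axis) in each analysis setting, with genes higher in HFpEF in red and genes lower in HFpEF in blue. Counts run from 6 genes with the replicate number as a block to 1247 with DESeq2, and rising genes outnumber falling genes in every bar.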

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

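The call of 316 genes (251 higher, 65 lower) stayed within 1.5 times under RLE scaling, upper quartile scaling, both filters on low counts and robust = TRUE, and without the 10 most counted genes or the genes with non-whole expected counts. The last 2 were chosen after seeing the data. limma-voom gave 223 genes with 37 lower, and with sample weights 453 with 112 lower. DESeq2 gave 1247 (861 higher, 386 lower). On simulated counts, in which few genes were changed, it called more unchanged genes than edgeR did, which need not carry over to these data. A threshold of 0.1 gave 943 (668 higher, 275 lower). With 1 surrogate variable 138 genes were called (124 higher, 14 lower), of which 129 were among the 316; the cause was not tested. Leaving out 1 library gave 22 to 332 genes, 21 to 234 higher and 0 to 98 lower, with fewer libraries in the test. The 0 lower genes came without Control replicate 3, where edgeR gave 2522 genes an unadjusted p under 0.05 in either direction. The difference in total counts (HFpEF minus Control) ran from -2997147 to -1195401 when 1 library was left out. Without HFpEF replicate 1 its exact permutation p was 0.0286, and otherwise it missed 0.05.

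The replicate block left 6 genes, all higher and 0 lower, with 2568 genes at an unadjusted p under 0.05. Deviations from the group means in same-numbered libraries correlated at -0.022, -0.056, 0.068 and -0.162, and 2 of 8 libraries correlated best with their own number, so the numbers were not taken to pair the libraries. No set test of a gene list was run, under any alternative, because the identifiers were not paired with names.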

Other observations

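Chosen after the result was seen were the tests of other splits of the libraries, of genes with few counts and of a single library behind the excess of rising genes. The other tests were fixed before their own result was seen. Among 22 sets of 4 values for single libraries (library measures and the 4 named genes), 0 held a value standing apart by Dixon's test. With 4 values this test finds only extreme cases, so it does not show that no library stood apart. Control replicate 4 lay 21.0 from its group centre, against 13.88 to 15.02 for the other Control libraries.

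Of the 35 splits of the 8 libraries into 4 and 4, only the real one (1 of 35) gave as many called genes. It gave 316, and the highest other split gave 25, with Control replicates 1, 2 and 3 and HFpEF replicate 4 on one side. A share of 1 of 35 is the smallest that these splits allow, and the test was chosen after the result was seen. Chance assignment of libraries to groups is therefore argued against but not excluded.

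A first pattern is that 79.4% of called genes were higher in HFpEF. Wider sets of genes were less uneven, with 70.8% higher at a threshold of 0.1 and 57.3% among genes with an unadjusted p under 0.05. The pattern is therefore one of the called genes and not of a broad rise. Genes with few counts are argued against as the whole cause, because among 128 called genes with at least 16 mean CPM, a bound set after seeing the result, 69.5% were higher, and 61.3% to 100% when each library was left out; above 64 CPM the called genes were too few to show an uneven split. The share was at least 70.5% without each library in turn, but this cannot decide whether a single library caused the excess. Many genes called then were already among the 316, whose direction could hardly reverse. They were 22 of 22 without Control replicate 1 and 211 of 332 without HFpEF replicate 1. The scaling of the libraries stays open: the share was 78.8% under upper quartile scaling, but this and RLE scaling moved the log2 fold changes by a median of at most 0.0032, too little to test it. A change in the mix of cell types and a change within cells also stay open and were not tested, because marker genes could not be named.

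A second pattern is that HFpEF libraries spread more around their group mean than Control libraries. Over 9713 genes with at least 8 mean CPM, the median variance of log2 CPM was 0.0162 in HFpEF and 0.00768 in Control, a ratio of 2.11. Counting noise is argued against, since the ratio was 3.38 in the 1652 genes with a mean of at least 3000 counts. HFpEF replicate 2 alone is not the whole cause, with a ratio of 1.76 without it; without Control replicate 4, which lay 21.0 from its group centre against 13.88 to 15.02 for the other Control libraries, the ratio was 3.25. Chance stays open: distances to the group centre were 21.7 ± 1.31 in HFpEF and 16.2 ± 3.25 in Control (SD, n = 4 each), with an exact two-sided permutation p of 0.0571, and disease that advanced unevenly between rats may add to it but was not tested.

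In a further pattern, 10 genes lay near 0 in 1 library while well detected in the other 7; near 0 meant over 16 times below the median of the other libraries, which had to be at least 4 CPM with none of the others over 4 times below it. Reads shared between near-identical genes, which RSEM may assign almost wholly to 1 copy, are a candidate explanation. Of these 10 genes, 90.0% (9) had a non-whole expected count, against 30.4% of 11588 other genes of that level (Fisher's exact test, two-sided, p = 0.000161). A low-yield library is argued against by the totals, which ran only from 31774820 to 38889395, while a drop of over 16 times was required. Which library held these genes could add little to that. HFpEF replicate 2, with the fewest counts, had 0 such genes and Control replicate 4 had 3. None of the 10 genes was among the 316, and 92 of the 316 (29.1%) had a non-whole count against 32.2% of tested genes.

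A set of genes varied together within the groups, for 30 of them mainly through a high level in HFpEF replicate 2. Of 492 genes with a within-group SD of at least 0.5 on the log2 scale, 43 correlated over 0.9 with their first shared component, and 0 of 100 shufflings within groups gave as many (highest 25). The 30 of them that moved in one direction had a mean level in HFpEF replicate 2 that was 11.2 times the lowest library's, against 1.53 to 2.38 times in the other HFpEF libraries and up to 1.23 times in Control. Their correlation therefore rests largely on HFpEF replicate 2. Shuffling breaks the tie between genes, so a single library that stands apart can exceed the shuffled counts. The 30 genes were chosen for this pattern, and 0 of them were called between the groups by edgeR. They were picked for a large spread within groups, which makes a call harder to reach. The 0 calls therefore do not show that the set was alike in both groups. Its mean log2 CPM lay between 1.31 and 4.17 in the HFpEF libraries and between 0.69 and 0.99 in the Control libraries. This difference was not tested for the set as a whole.

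The 2 most counted genes held 12.9% of all counts, and their counts stood in a ratio of 0.992 to 1.02 in every library, with non-whole values in both. Their log2 fold changes were 0.30 and 0.30 (edgeR adjusted p = 0.290 and 0.305). One of the 15 most counted genes, chosen as the most variable within groups, stood at 17190 and 21100 CPM in Control replicates 2 and 3 and between 2615 and 6331 CPM in the other 6 libraries (edgeR adjusted p = 0.153). It too had a non-whole expected count, so the sharing of reads between genes cannot be told apart from expression as the source.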
